A study of Mus musculus with 12 samples.

How the data were processed

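RNA was sequenced from bone marrow LSK cells of mice. LSK cells are lineage-negative cells that carry Sca1 and c-Kit on their surface, the fraction of marrow that holds haematopoietic stem cells and early progenitors. The series has 12 libraries, 4 from each of 3 genotypes: Yy1+/+, Yy1-/- and Yy1-/- Smc3+/-. Per the labels' protocols, RNA of the sorted cells was purified with the RNeasy Micro kit, and the libraries were made with the SMART-Seq v4 ultra-low-input kit, which copies full-length cDNA by PCR and does not mark the strand. The labels give no sex, age, day, batch or number of animals per library, and nothing that pairs a library of one genotype with a library of another.

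The tools named for these files, per the submitters' processing notes, are STAR 2.5.2b and RSEM 1.3.0, with the genome build mm10. The settings, the role of each tool and the annotation release were not given in the sources used here. Per the file headers, each deposited table is an RSEM gene table. Its expected count is the estimated number of reads or fragments of a gene, without scaling for depth or length. Reads that match several genes are divided between them, so some deposited expected counts lay more than 1e-06 away from a whole number. These were between 6.4% and 7.1% of all 55487 genes listed for a library, those with 0 counts included. Only between 17214 and 20005 genes of a library had at least 1 count, so the share among genes with reads was higher. The deposited TPM column holds transcript abundance corrected for length and scaled to the same sum in every library, and the deposited FPKM column, which no result here uses, holds fragments scaled by length and depth. The effective length column, per the file headers, was used only for an alternative that corrects for length.

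Each table lists 55487 genes by Ensembl identifier. Symbols and positions were taken from the GENCODE M21 annotation of the mouse build GRCm38, the assembly also called mm10. The identifier matched with its version for 55094 genes and with another version for 300. The other 93 genes did not match. The summed expected count was between 38671354 and 69086104 per library, and the deepest library stood apart from the next one at 51587192. Where all libraries of a genotype had 0 counts of a gene, the fold change is given as a bound computed from 3 counts over the whole group, which is 0.0145 CPM in Yy1+/+, 0.0171 in Yy1-/- and 0.018 in Yy1-/- Smc3+/-. These bounds and the counting intervals, at a level of 95%, cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

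Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by its filter with a minimum count of 10 and a minimum total of 15, which left 16649 genes. Libraries were scaled by TMM factors, and 1 quasi-likelihood model with a term for each genotype was fitted to all 12 libraries. Each of the 3 pairs of genotypes was tested with the quasi-likelihood F test. A gene is described as having risen, fallen or changed when its Benjamini-Hochberg adjusted p was under 0.05. Levels are counts scaled to a common library size with the TMM factors (CPM), given as mean and standard deviation (SD) over n = 4 libraries, and log2 fold changes are given with the standard error (SE) of the model. The p-values of this F test measure the spread between these libraries.

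Before the data were examined, 44 gene lists were fixed, covering pathways, protein complexes, blood and marrow cell types, and signs of tissue dissociation. The design, the tests, the rule for naming genes and most alternatives were fixed at the same time. The list of sex-linked genes was described and not tested. The other 43 lists were tested with camera of limma 3.58.1, a test that compares a list with all other genes, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. At this preset the p-value of camera takes genes as its units, so it does not by itself measure the spread between libraries. Camera with a correlation estimated from the data, camera on ranks and fry were run beside this test. Member counts are given over all genes tested and adjusted over the list alone. Medians are log2 fold changes over all measured members of a list. Some genes stand in more than 1 list. The genes named are Yy1 and Smc3; for each comparison, the 10 largest rises and 10 largest falls among changed genes with a mean of at least 5 CPM in the higher genotype and no overlap between the libraries of the 2 genotypes; up to 4 changed members with the smallest p of each list described; the 8 genes with the smallest p among any that moved back; and the 3 members with the highest mean of the lists of cell types and quality. The first kind leaves out sex-linked, mitochondrially encoded, immunoglobulin and T cell receptor genes and symbols that are only a clone, predicted or pseudogene name. Some genes that meet the rule are not reported here. Genes named outside this rule are marked as chosen after their values were seen, except members that are named only because a count of a list was 5 or fewer, all of which were chosen after their values were seen.

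The test was checked on simulated counts drawn from the means and library sizes of these data, in 5 draws with 200 genes changed in each. For Yy1-/- against Yy1+/+, over 16148 genes, edgeR recovered 24.5% of the genes changed 2-fold and 66% of those changed 4-fold, and 10.3% of its calls were false. For Yy1-/- Smc3+/- against Yy1+/+, over 16151 genes, it recovered 26.4% and 61.7%, with 8.8% of calls false. For Yy1-/- Smc3+/- against Yy1-/-, over 16145 genes, it recovered 25.6% and 67.8%, with 6.8% of calls false. The share of false calls was thus above the nominal level in these draws. With DESeq2 it was 31%, 26.4% and 29.3%, with the edgeR 3 style 4.2%, 3.6% and 2.3%, and with limma-voom 3.4%, 2.5% and 1.4%. The edgeR 3 style recovered 22.2%, 25% and 23.1% of the genes changed 2-fold, and limma-voom 22.2%, 24.6% and 23.5%. Of 11 simulated lists, camera called the 1 changed list and 0 of the 10 unchanged ones. Each gene was drawn independently, so this check could not show false calls of lists whose members move together. In these data the correlation estimated within the list of cytosolic ribosomal proteins was 0.817 for Yy1-/- against Yy1+/+.

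The alternatives were DESeq2 1.42.0, limma-voom, limma on log2 of the deposited TPM plus 1 for genes with a TPM of at least 1 in 4 libraries, other scaling factors, an offset for effective length, no filter or a stricter one (1 CPM in 4 libraries and a mean count of 20), the edgeR 3 style of the test, a robust fit, a fit of only the 2 genotypes compared, a surrogate variable from sva 3.50.0 or the Xist level as a covariate, a 2-fold minimum, and each library left out in turn. Others were added after the data were seen: leaving out the libraries with residual Yy1 reads, leaving out a pair of libraries that stand apart, leaving out immunoglobulin genes, the level of granule genes as a covariate, and, for the counts of genes, a block of replicates 1 and 2 against 3 and 4 in the 2 genotypes labelled Yy1-/-. Overlap between comparisons that share a genotype was set against 20 simulated draws and against fits in which the shared libraries were split between the comparisons. Pseudogene transcripts were matched to their parent genes with blastn 2.17.0. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the main results.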

Results

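Gene expression was measured by RNA sequencing of LSK cells sorted from mouse bone marrow, with 4 libraries for each of 3 genotypes. Yy1+/+ mice served as the wild-type control. The second group is labelled Yy1-/-, and Yy1 encodes Yin Yang 1, a zinc finger protein that binds DNA and can act both as an activator and as a repressor of transcription. The third group is labelled Yy1-/- Smc3+/-, and Smc3 encodes a core subunit of the cohesin ring. The summed expected counts were 50140940, 69086104, 43213036 and 42071439 in Yy1+/+ replicates 1 to 4, 44111897, 51587192, 45285633 and 40937638 in Yy1-/- replicates 1 to 4, and 45761793, 42173608, 39167210 and 38671354 in Yy1-/- Smc3+/- replicates 1 to 4. A library had between 17214 and 20005 genes with at least 1 count. On the first principal component of the log CPM, which held 40.6% of the variance, the Yy1+/+ libraries lay between -119.8 and -108.7 and all others between 31.7 and 112.9. Yy1-/- replicate 1 stood apart on the second component, at 114.8. The median correlation across genes was 0.953 between Yy1+/+ libraries, 0.927 between Yy1-/- libraries and 0.94 between a Yy1-/- and a Yy1-/- Smc3+/- library.

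Yy1 mRNA (ENSMUSG00000021264.12, chromosome 12:108792973-108820148, GRCm38) was low in all libraries labelled Yy1-/- but not absent from any. Its level was 35.8 ± 3.63 CPM (SD, n = 4) in Yy1+/+, 4.65 ± 5.43 in Yy1-/- and 1.74 ± 1.81 in Yy1-/- Smc3+/-. Yy1 fell to 13% of the Yy1+/+ mean in Yy1-/- (log2 fold change -2.96 ± 0.67 SE, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.00453) and to 4.85% in Yy1-/- Smc3+/- (-4.4 ± 0.76, edgeR adjusted p = 0.000948). The reads that remained were unequal between libraries, with 5.01 and 12.2 CPM in Yy1-/- replicates 3 and 4 and 4.45 CPM in Yy1-/- Smc3+/- replicate 3, against 0.407 to 0.996 CPM in the other 5 libraries labelled Yy1-/-. The log2 fold change was -4.09 without Yy1-/- replicate 4 and -5.42 without Yy1-/- Smc3+/- replicate 3. The gene tables hold no exon counts, so reads from a part of Yy1 outside a deletion cannot be told apart from reads of an intact gene.

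Smc3 mRNA (ENSMUSG00000024974.10, chromosome 19:53600398-53645833, GRCm38) was higher in both groups labelled Yy1-/- than in Yy1+/+, and it was not lower in the libraries labelled Yy1-/- Smc3+/-. Its level was 177 ± 25.2 CPM (SD, n = 4) in Yy1+/+, 255 ± 45.2 in Yy1-/- and 301 ± 38.1 in the libraries labelled Yy1-/- Smc3+/-. Smc3 rose in Yy1-/- against Yy1+/+ (log2 fold change 0.53 ± 0.15 SE, edgeR adjusted p = 0.0167) and in the libraries labelled Yy1-/- Smc3+/- against Yy1+/+ (0.76 ± 0.15, edgeR adjusted p = 0.00254). Between the libraries labelled Yy1-/- Smc3+/- and Yy1-/- the log2 fold change of Smc3 was 0.24, with a 95% interval of -0.09 to 0.56 (edgeR adjusted p = 0.819), so the interval leaves out a halving of the mRNA. The rise of Smc3 in Yy1-/- lost its call with log2 TPM (0.24, adjusted p = 0.346), without the libraries with residual Yy1 reads (0.39, adjusted p = 0.168), without Yy1+/+ replicate 1 (0.49, adjusted p = 0.0517) and without Yy1-/- replicate 3 (0.40, adjusted p = 0.0734), within a range of adjusted p from 0.00714 to 0.346 over its alternatives. The gene tables cannot show whether an altered Smc3 allele still makes a transcript that is counted. Because the mRNA does not set the Smc3+/- label apart, the third genotype is named below as labelled.

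**Figure D1:**
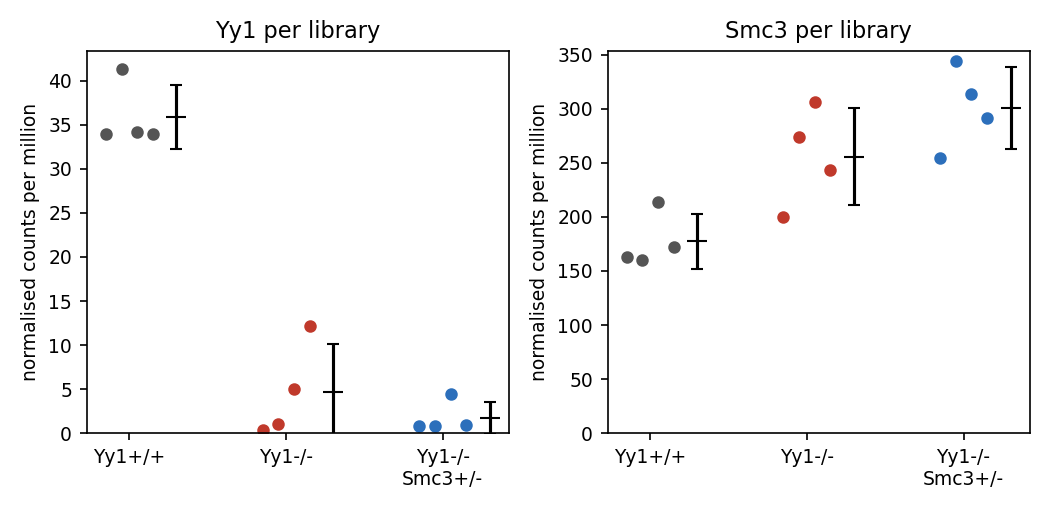
Levels of Yy1 and Smc3 in TMM-normalised CPM for each library (points) by genotype, with the mean and SD of n = 4 libraries. Yy1 lies between 33.9 and 41.3 in Yy1+/+ and at or below 12.2 in all other libraries, while the mean of Smc3 is 177 in Yy1+/+, 255 in Yy1-/- and 301 in the libraries labelled Yy1-/- Smc3+/-.

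The comparison of Yy1-/- with Yy1+/+ asks which genes differ between LSK cells with these labels. Genes of haematopoietic stem cells were lower in Yy1-/- and genes of mitosis were higher. Of 50 measured stem cell genes 42 fell and 2 rose, with a median log2 fold change of -2.13, and of 51 measured genes of mitosis and the G2/M phase 46 rose and 0 fell, with a median of 1.07. The lists of ribosomal protein and proteasome genes had medians above 0, and those of erythroid, megakaryocyte, Hox and imprinted genes medians below 0. With an estimated correlation only the last of these 6 lists passed camera, with adjusted p = 0.0483 against 0.301 to 0.638 for the others. In all, 5854 of 16649 tested genes changed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 2722 higher and 3132 lower in Yy1-/-. Of all tested genes, 30.9% had no overlap between the 4 and the 4 libraries, against 2.9% by chance.

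The stem cell genes that fell included surface receptors and regulators that mark long-term stem cells. Pdzk1ip1, a membrane protein gene, fell from 95.2 ± 17.7 to 2.03 ± 0.977 CPM (SD, n = 4; log2 fold change -5.54 ± 0.32 SE, edgeR adjusted p = 5.63e-07). Mllt3, a chromatin reader that maintains stem cells, fell by a log2 fold change of -3.11 ± 0.24 (edgeR adjusted p = 3.51e-06), Tek, the angiopoietin receptor, by -3.99 ± 0.34 (7.95e-06) and Tcf15, a transcription factor of quiescent stem cells, by -4.93 ± 0.45 (7.95e-06). The 2 list members that rose were Ifitm1 (1.15 ± 0.2, edgeR adjusted p = 0.000849) and Ifitm3 (0.67 ± 0.21, 0.0264), chosen after their values were seen. Ly6a, which encodes the Sca1 protein of the sort, did not pass the test (0.43 ± 0.26, edgeR adjusted p = 0.215), while Kit, which encodes the c-Kit protein of the sort, fell from 769 ± 243 to 176 ± 69.8 CPM (-2.12 ± 0.33, edgeR adjusted p = 0.000455), both chosen after their values were seen. The list passed camera at adjusted p = 2.01e-27, and with an estimated correlation at adjusted p = 0.0207. Adjusted over the list alone, 42 fell and 2 rose.

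Most genes of mitosis rose, and the median change of the list was about 2-fold. Cdk1, the kinase that drives entry into mitosis, rose from 128 ± 16.7 to 317 ± 37.4 CPM (SD, n = 4; log2 fold change 1.31 ± 0.13 SE, edgeR adjusted p = 2.53e-05), and Cenpa, the centromeric histone, rose by 1.26 ± 0.12 (1.85e-05). The list passed camera at adjusted p = 4.89e-30 (adjusted p = 0.222 with an estimated correlation), and 48 members rose adjusted over the list alone. Of 14 measured genes of condensin and the SMC5/6 complex, the ring complexes related to cohesin, 8 rose and 0 fell, also adjusted over the list alone. Their median was 0.52 (camera adjusted p = 5.02e-05; adjusted p = 0.269 with an estimated correlation). Ncaph, a condensin subunit, rose by 1.22 ± 0.15 (edgeR adjusted p = 6.92e-05). Of 49 genes of DNA replication 16 rose and 1, Mcm2, fell, as also adjusted over the list alone. Their median was 0.24 (camera adjusted p = 0.0246; adjusted p = 0.768 with an estimated correlation). This call was lost with log2 TPM (0.219), without the libraries with residual Yy1 reads (0.89), and without Yy1+/+ replicate 1 (0.123), Yy1-/- replicate 3 (0.162) or Yy1-/- replicate 4 (0.141), with camera adjusted p between 0.00155 and 0.89 over the alternatives.

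Genes for making and degrading protein and for respiration were higher. Of 81 genes for cytosolic ribosomal proteins 72 rose and 0 fell, with a median of 0.72, and 77 rose adjusted over the list alone (camera adjusted p = 8.49e-24; adjusted p = 0.479 with an estimated correlation). Rps27l had the smallest p of them (log2 fold change 1.47 ± 0.17 SE). Of 38 proteasome genes 26 rose and 0 fell, 29 rose adjusted over the list alone. Their median was 0.60 (camera adjusted p = 5.44e-11; adjusted p = 0.513 with an estimated correlation). Psmb7, a catalytic subunit, rose by 1.13 ± 0.13 (edgeR adjusted p = 4.32e-05). Of 78 genes for mitochondrial ribosomal proteins 40 rose and 1, Mrpl42, fell, 46 and 1 adjusted over the list alone. Their median was 0.44 (camera adjusted p = 6.7e-10; adjusted p = 0.638 with an estimated correlation). Of 77 nuclear genes of oxidative phosphorylation 44 rose and 4 (Ndufc1, Sdha, Sdhc and Uqcrc1) fell, 49 and 5 adjusted over the list alone. Their median was 0.49 (camera adjusted p = 8.11e-11; adjusted p = 0.638 with an estimated correlation). Atp5l, a subunit of ATP synthase, rose by 1.15 ± 0.12 (edgeR adjusted p = 3.62e-05). On the scale of log2 TPM the median of all genes lay at -0.230 for Yy1-/- and -0.148 for Yy1-/- Smc3+/- against Yy1+/+. These 4 lists kept their direction and passed camera with the preset correlation in all alternatives in which they were tested.

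Genes of the megakaryocyte and erythroid lines were lower. Mmrn1, a platelet granule protein gene, fell from 159 ± 19.4 to 1.86 ± 1.03 CPM (SD, n = 4; log2 fold change -6.45 ± 0.61 SE, edgeR adjusted p = 1.69e-05). Of 28 megakaryocyte genes 15 fell and 2 (Clec1b and Sla) rose, 18 and 2 adjusted over the list alone. Their median was -1.07 (camera adjusted p = 0.000306; adjusted p = 0.479 with an estimated correlation). Of 30 erythroid genes 13 fell and 0 rose, as also adjusted over the list alone. Their median was -1.57 (camera adjusted p = 0.000279; adjusted p = 0.638 with an estimated correlation). Car2, a carbonic anhydrase of the red cell line, fell from 1480 ± 243 to 217 ± 137 CPM (-2.77 ± 0.39, edgeR adjusted p = 0.000198). Car1 had 0 CPM in Yy1-/- replicates 1 and 2 but 201 and 39.7 CPM in replicates 3 and 4, the libraries with more residual Yy1 reads.

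Developmental and imprinted genes were lower. Of 16 Hox genes 9 fell and 0 rose, as also adjusted over the list alone. Their median was -1.28 (camera adjusted p = 0.000961; adjusted p = 0.301 with an estimated correlation). Hoxa9, which supports stem cell renewal, fell by a log2 fold change of -1.52 ± 0.23 SE (edgeR adjusted p = 0.000347), and the counts of Hoxa2 were 148-fold lower (95% counting interval 40.8 to 1230), with a larger fall without Yy1-/- replicate 3. Of 17 imprinted genes 11 fell and 0 rose, as also adjusted over the list alone. Their median was -1.88 (camera adjusted p = 7.13e-07, and 0.0483 with an estimated correlation). They included Grb10, an adaptor that restrains growth signals (-3.86 ± 0.34, edgeR adjusted p = 1.09e-05), and the non-coding RNA Meg3, which was at least 117-fold lower. Of 36 genes of Polycomb complexes and YY1 partners 15 fell and 4 (Ezh2, Ino80, Actr8 and Yy2) rose, as also adjusted over the list alone. Their median was -0.42 (camera adjusted p = 0.0345; adjusted p = 0.551 with an estimated correlation). Rnf2, the ubiquitin ligase of Polycomb repressive complexes, fell by -1.48 ± 0.15 (edgeR adjusted p = 2.53e-05). The Polycomb call was lost with log2 TPM (0.072), the stricter filter (0.0921) and a fit of only the 2 genotypes (0.0697), with camera adjusted p between 0.00311 and 0.0921 over the alternatives.

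The lists of monocyte and neutrophil genes had medians above 0, and the size of the rise differed between Yy1-/- libraries. Of 34 monocyte, macrophage and dendritic cell genes 20 rose and 1, Flt3, fell, 23 and 2 adjusted over the list alone. Their median was 2.21 (camera adjusted p = 9.19e-05; adjusted p = 0.638 with an estimated correlation). Ms4a6c, a monocyte membrane protein gene, rose by a log2 fold change of 3.12 ± 0.41 SE (edgeR adjusted p = 0.00014), with 551, 265, 143 and 111 CPM in Yy1-/- replicates 1 to 4 and a log2 fold change of 2.46 without replicate 1. Of 30 neutrophil and granulocyte progenitor genes 13 rose and 0 fell, as also adjusted over the list alone. Their median was 1.09 (camera adjusted p = 0.00501; adjusted p = 0.679 with an estimated correlation). Of the 3 members with the highest mean, Ctsg, a granule protease gene, rose (2.22), while Mpo and Lyz2 did not pass the test. Mpo had a mean of 4170 CPM in Yy1+/+ and 1990 in Yy1-/-, and Lyz2 had 4250, 2810, 177 and 348 CPM in Yy1-/- replicates 1 to 4 against a mean of 596 in Yy1+/+. Of 50 interferon-stimulated genes 16 rose and 2 (Ifi44 and Ifih1) fell, as also adjusted over the list alone. Their median was 0.47 (camera adjusted p = 0.0065; adjusted p = 0.768 with an estimated correlation). Ifi27l2a rose by 4.56 ± 0.7 (edgeR adjusted p = 0.00037), with 304 and 192 CPM in Yy1-/- replicates 1 and 2 against 29.5 and 37.4 in replicates 3 and 4 and a log2 fold change of 3.83 without replicate 1. The interferon call was lost without Yy1-/- replicate 1 (0.152), without the pair of libraries that stand apart (0.276) and with granule gene level as a covariate (0.0713), with camera adjusted p between 1.36e-14 and 0.276 over the alternatives. Of 31 genes of T, NK and innate lymphoid cells 13 rose and 2 (Lat and Rora) fell, 14 and 2 adjusted over the list alone. Their median was 1.47 (camera adjusted p = 0.00901; adjusted p = 0.642 with an estimated correlation). Trac and Cd3g of the T cell receptor complex rose by 6.12 and 3.76, from 0.0273 to 2.23 and from 0.46 to 6.75 CPM, and Cd3g by 4.51 without Yy1+/+ replicate 2. The 3 members with the highest mean were lower: Lat, an adaptor of that receptor, fell from 46.6 to 15.2 CPM, and Nkg7 (186 and 68.8 CPM) and Lck (42.9 and 21.5 CPM) did not pass the test. The T and NK call was lost without the libraries with residual Yy1 reads (0.42), with camera adjusted p between 0.00111 and 0.42 over the alternatives.

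Among stress genes, the list of p53 targets had a median above 0 and that of immediate early genes a median below 0. Of 34 p53 targets 10 rose and 5 (Sesn1, Btg2, Plk2, Gadd45a and Xpc) fell, as also adjusted over the list alone. Their median was 0.31 (camera adjusted p = 0.00366; adjusted p = 0.479 with an estimated correlation). Phlda3, a repressor of AKT, rose by a log2 fold change of 2.73 ± 0.25 SE (edgeR adjusted p = 1.34e-05), and Bax, which permeabilises mitochondria in apoptosis, rose by 1.34 ± 0.19 (0.00026). Of 35 immediate early and dissociation genes 19 fell and 0 rose, 25 fell adjusted over the list alone. Their median was -2.33 (camera adjusted p = 0.000101; adjusted p = 0.658 with an estimated correlation). Dnajb1, a heat shock co-chaperone gene, fell by -2.58 ± 0.58 (edgeR adjusted p = 0.00437), from levels of 357, 1619, 137 and 347 CPM in Yy1+/+ replicates 1 to 4, and by -1.45 without replicate 2. Myc fell by -0.89 ± 0.17 (edgeR adjusted p = 0.00159). The 3 members with the highest mean varied widely within Yy1+/+, and their ranges overlapped those in Yy1-/-. Jun had 178 to 4070 CPM in Yy1+/+ and 64.7 to 1010 in Yy1-/-. Fos had 90 to 3070 and 31.3 to 765 CPM, and Dusp1 71.8 to 2180 and 31.9 to 399 CPM.

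Smaller or less certain shifts were seen in cholesterol synthesis, histone and DNA repair genes. Of 24 cholesterol synthesis genes 10 fell and 2 (Pmvk and Ebp) rose, 12 and 2 adjusted over the list alone (camera adjusted p = 0.0111; adjusted p = 0.638 with an estimated correlation), among them Insig1, a sterol sensor (log2 fold change -1.29 ± 0.16 SE, edgeR adjusted p = 8.83e-05), and the call was lost with log2 TPM (0.0632, in a range from 0.000874 to 0.0632). Of 20 histone genes 10 rose and 2 (Hist2h2be and H1fx) fell, 11 and 3 adjusted over the list alone. Their median was 0.64 (camera adjusted p = 0.0226; adjusted p = 0.479 with an estimated correlation), and H2afz, a variant histone gene, rose by 1.16 ± 0.17 (edgeR adjusted p = 0.000313). The histone call was lost without the libraries with residual Yy1 reads (0.107), Yy1+/+ replicate 1 (0.0512) or Yy1-/- replicate 3 (0.053), in a range from 0.00176 to 0.107. Of 44 DNA repair genes 12 rose and 4 (among them Rad52, Xrcc4 and Trp53bp1) fell, as also adjusted over the list alone, with a median of 0.23 and a camera adjusted p just under 0.05 that was lost in 12 of 25 alternatives, in a range from 0.00296 to 0.42, among them the omission of Yy1+/+ replicate 1 (0.0964), 2 (0.171) or 4 (0.053) and of Yy1-/- replicate 3 (0.0694) or 4 (0.175) (adjusted p = 0.72 with an estimated correlation). Of 21 genes of cohesin and its regulators 6 rose and 2 (Esco1 and Rec8) fell, 8 and 2 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0515; adjusted p = 0.642 with an estimated correlation). Sgo1, the protector of centromeric cohesin, rose by 1.52 ± 0.15 (edgeR adjusted p = 2.44e-05), and Rec8, the meiotic kleisin, fell by -2.59 ± 0.28 (3.67e-05).

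The genes with the largest rises and falls in Yy1-/- were of several kinds. Stfa2 and Stfa3, stefin genes of the neutrophil line, were at least 503-fold and at least 410-fold higher in Yy1-/-, and Stfa2l1 and Stfa1 rose by log2 fold changes of 8.36 and 7.9. Counts of Ednrb, the endothelin B receptor gene, were 3100-fold higher (95% counting interval 556 to 122000). Fpr1, a receptor for bacterial peptides, rose by 7.32, Dab2, an endocytic adaptor, by 7.19, Ms4a4a by 7.01, the complement receptor C3ar1 by 6.91 and ceruloplasmin, Cp, by 6.76. Epx was at least 11800-fold lower, Ear6 at least 691-fold and Ear1 at least 652-fold, and Prg3 fell by a log2 fold change of -8.73 and Prss34 by -7.54. The fixed list of mast cell, basophil and eosinophil genes did not pass camera (adjusted p = 0.643). Foxa3 was at least 362-fold lower, and Ccdc60 fell by -7.85, Vnn1 by -7.83 and the amino acid transporter Slc6a15 by -7.39. Levels of some of these genes varied widely within a genotype, as for Epx with 146, 589, 48.3 and 19.5 CPM in Yy1+/+ replicates 1 to 4. Without Yy1+/+ replicate 2, Epx was at least 4190-fold lower, Ear6 at least 342-fold and Ear1 at least 365-fold, Prg3 had -7.46 and Prss34 -6.86. Without Yy1-/- replicate 1, Fpr1 had 5.93, C3ar1 5.77, Cp 5.7 and Ms4a4a 6.13. Without Yy1-/- replicate 2, Stfa2 was at least 262-fold and Stfa3 at least 142-fold higher, and Stfa2l1 had 7.32, Stfa1 6.88, Dab2 6.28 and Ednrb 10.08. Changes were more than 1.5 times larger without Yy1+/+ replicate 1 for Stfa2l1 (11.35), Stfa1 (9.56), Fpr1 (9.67), Dab2 (8.05), Cp (7.35) and Ednrb (12.33), without Yy1-/- replicate 3 for Ccdc60 (-11.1), Vnn1 (-9.08) and Prss34 (-8.81), and without replicate 4 for Prg3 (-10.22) and Slc6a15 (-8.21). With limma-voom 9 of these genes, Stfa1, Fpr1, Dab2, Ms4a4a, C3ar1, Cp, Epx, Prg3 and Prss34, lost their call, with adjusted p from 0.0643 for Stfa1 to 0.247 for Dab2, and the range for Dab2 over its alternatives was 2.28e-05 to 0.247.

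**Figure D2:**
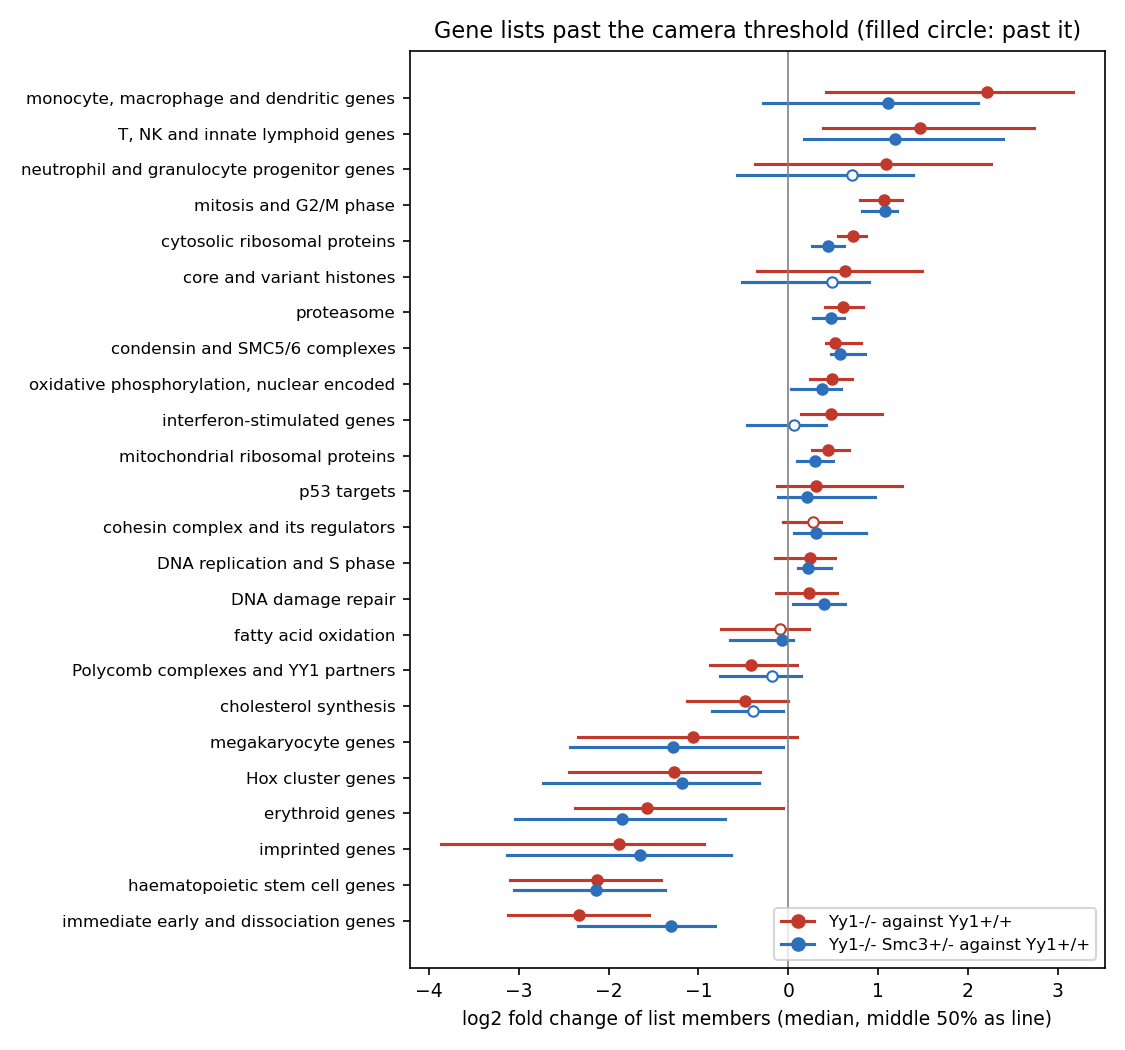
Median log2 fold change of the members of each list that passed camera in at least 1 comparison against Yy1+/+ (circles, filled where the list passed; lines span the middle 50% of the members), with positive values higher than in Yy1+/+. Stem cell genes have a median of -2.13 in Yy1-/- and -2.15 in Yy1-/- Smc3+/-, and mitotic genes 1.07 and 1.08.

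Of the 43 lists tested, 22 passed camera in Yy1-/- against Yy1+/+, 14 higher and 8 lower, and with an estimated correlation only stem cell and imprinted genes did. No median of a list changed when members with 0 counts in a genotype were set at their bounds. The number of changed genes was between 4855 and 6027 over the alternatives other than a 2-fold minimum, with which it was 3399. The share of changed genes that were higher was 46.5%, and 26.3% with log2 TPM.

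The comparison of Yy1-/- Smc3+/- with Yy1+/+ asks which of these differences are also seen in the libraries with the Smc3+/- label. Stem cell genes were again lower and mitotic genes again higher. Of 50 stem cell genes 43 fell and 1 rose, also adjusted over the list alone, with a median log2 fold change of -2.15, and 48 of 51 mitotic genes rose, also adjusted over the list alone, with a median of 1.08. In all, 4975 of 16649 genes changed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 2189 higher and 2786 lower, and 32.2% of tested genes had no overlap between libraries, against 2.9% by chance. Xist, the transcript of the inactive X chromosome, had 0, 3.58, 107 and 0 CPM in the libraries labelled Yy1-/- Smc3+/- and at least 31.2 CPM in each Yy1+/+ and Yy1-/- library, and with the Xist level as a covariate 2427 genes changed. Both Xist and Y-linked reads were present in Yy1+/+ replicates 1 and 4, Yy1-/- replicate 3 and Yy1-/- Smc3+/- replicates 2 and 3, with 111, 101, 38.9, 135 and 28.7 CPM of Y-linked genes, so the Xist level does not give the sex of these libraries.

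Pdzk1ip1 fell by a log2 fold change of -5.13 ± 0.31 SE (edgeR adjusted p = 6.22e-07) in Yy1-/- Smc3+/-, and the 1 stem cell gene that rose was Ifitm1 (0.89, edgeR adjusted p = 0.00482), chosen after its value was seen. The stem cell list passed camera at adjusted p = 6.09e-30, and with an estimated correlation at adjusted p = 0.0182. Among mitotic genes, Cdc25c, the phosphatase that activates Cdk1, rose by 1.66 ± 0.17 (edgeR adjusted p = 2.92e-05) and the list passed at camera adjusted p = 3.82e-34 (adjusted p = 0.162 with an estimated correlation). Of 14 condensin and SMC5/6 genes 10 rose and 0 fell, also adjusted over the list alone. Their median was 0.58 (camera adjusted p = 6.09e-06; adjusted p = 0.165 with an estimated correlation). Ncaph rose by 1.29 ± 0.15 (edgeR adjusted p = 5.53e-05). Of 49 DNA replication genes 15 rose and 0 fell, 16 rose adjusted over the list alone. Their median was 0.22 (camera adjusted p = 0.00163; adjusted p = 0.734 with an estimated correlation). Of 44 DNA repair genes 14 rose and 3 (among them Rad52 and Xrcc4) fell, 16 and 3 adjusted over the list alone. Their median was 0.40 (camera adjusted p = 0.00174; adjusted p = 0.63 with an estimated correlation).

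Genes of cohesin and its regulators passed the list test in this comparison. Of 21 genes 8 rose and 2 (Esco1 and Rec8) fell, 9 and 2 adjusted over the list alone. Their median was 0.31 (camera adjusted p = 0.00468; adjusted p = 0.597 with an estimated correlation). Besides Smc3, the genes that rose included Sgo1 (log2 fold change 1.61 ± 0.15 SE, edgeR adjusted p = 1.79e-05), the meiotic cohesin subunit Stag3 (1.76 ± 0.25, 0.00027) and the cohesin kleisin Rad21 (0.86 ± 0.15, 0.000886), the last of which was chosen after its values were seen. The cohesin call was lost with log2 TPM (0.0614), in a range of camera adjusted p from 0.000306 to 0.0614 over the alternatives. Whether cohesin genes differ in their response between the genotypes was asked by the comparison of Yy1-/- Smc3+/- with Yy1-/-. None of them was among the 6 genes that changed there by edgeR. In that comparison the cohesin list had a median of 0.12 and did not pass camera (adjusted p = 0.0799, and 0.63 with an estimated correlation). It did pass camera on ranks (adjusted p = 0.0306), so the question stays open.

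Of 81 cytosolic ribosomal protein genes 43 rose and 1, Rps27, fell in Yy1-/- Smc3+/-, 47 and 1 adjusted over the list alone. Their median was 0.44 (camera adjusted p = 3.5e-11; adjusted p = 0.692 with an estimated correlation). Of 38 proteasome genes 23 rose and 0 fell, 24 rose adjusted over the list alone. Their median was 0.47 (camera adjusted p = 2.13e-07; adjusted p = 0.63 with an estimated correlation). Of 77 nuclear oxidative phosphorylation genes 31 rose and 4 (Ndufc1, Sdha, Sdhc and Uqcrc1) fell, 33 and 5 adjusted over the list alone. Their median was 0.36 (camera adjusted p = 5.05e-06; adjusted p = 0.734 with an estimated correlation). Of 78 mitochondrial ribosomal protein genes 24 rose and 4 (Mrpl27, Mrpl42, Mrpl50 and Mrps18b) fell, 27 and 4 adjusted over the list alone. Their median was 0.30 (camera adjusted p = 3.04e-05; adjusted p = 0.746 with an estimated correlation). Fatty acid oxidation genes, 9 of 23 lower and 1, Acaa1a, higher (9 and 2 adjusted over the list alone), had a median near 0 (-0.07) and a mean of -0.40 (camera adjusted p = 0.0399; adjusted p = 0.597 with an estimated correlation). That call was lost in 8 of 25 alternatives, among them the omission of Yy1+/+ replicate 2 (0.14) or Yy1-/- Smc3+/- replicate 4 (0.0553), in a range from 0.00332 to 0.14.

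The lists of megakaryocyte, erythroid, imprinted, Hox and immediate early genes had medians below 0 in Yy1-/- Smc3+/-. Of 28 megakaryocyte genes 16 fell and 0 rose, 18 fell adjusted over the list alone. Their median was -1.28 (camera adjusted p = 2.43e-06; adjusted p = 0.242 with an estimated correlation). Mmrn1 fell to 2.68 ± 2.46 CPM (SD, n = 4; log2 fold change -5.86 ± 0.58 SE, edgeR adjusted p = 2.54e-05). Of 30 erythroid genes 18 fell and 0 rose, 19 fell adjusted over the list alone. Their median was -1.86 (camera adjusted p = 3.61e-06; adjusted p = 0.597 with an estimated correlation). Car2 fell by -2.78 ± 0.39 (edgeR adjusted p = 0.000225). Of 17 imprinted genes 11 fell and 0 rose, as also adjusted over the list alone. Their median was -1.65 (camera adjusted p = 3.61e-06; adjusted p = 0.0906 with an estimated correlation). Of 16 Hox genes 7 fell and 0 rose, 8 fell adjusted over the list alone. Their median was -1.18 (camera adjusted p = 0.000437; adjusted p = 0.242 with an estimated correlation). Of 35 immediate early genes 10 fell and 0 rose, as also adjusted over the list alone. Their median was -1.30 (camera adjusted p = 0.00625; adjusted p = 0.77 with an estimated correlation). This call was lost in 4 of 25 alternatives, among them the omission of Yy1+/+ replicate 2 (0.14), in a range from 4.58e-07 to 0.227.

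Of 34 monocyte, macrophage and dendritic cell genes 11 rose and 1, Zbtb46, fell in Yy1-/- Smc3+/-, 14 and 1 adjusted over the list alone. Their median was 1.12 (camera adjusted p = 0.0194; adjusted p = 0.746 with an estimated correlation). The call was lost in 4 of 25 alternatives, among them the omission of Yy1+/+ replicate 3 (0.0848), in a range from 1e-05 to 0.125. Mpo, the myeloperoxidase of granulocyte progenitors, had 10100 CPM in Yy1-/- Smc3+/- replicate 3, which also held more Yy1 and Xist reads, and 565 to 981 CPM in the other 3. Of 31 T, NK and innate lymphoid genes 12 rose and 3 (Gata3, Lat and Rora) fell, as also adjusted over the list alone. Their median was 1.19 (camera adjusted p = 0.02; adjusted p = 0.73 with an estimated correlation), and the call was lost in 4 of 25 alternatives, among them the omission of Yy1+/+ replicate 3 (0.0559), in a range from 0.00035 to 0.0888. Of 34 p53 targets 10 rose and 4 (Sesn1, Plk2, Gadd45a and Ephx1) fell, as also adjusted over the list alone. Their median was 0.21 (camera adjusted p = 0.02; adjusted p = 0.597 with an estimated correlation), and the call was lost with the Xist level as a covariate (0.107, in a range from 0.00437 to 0.107). Phlda3 rose by a log2 fold change of 2.5 ± 0.25 SE (edgeR adjusted p = 2.57e-05).

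The largest rises in Yy1-/- Smc3+/- were in genes of several unrelated kinds. Counts of Ednrb were 1360-fold higher (95% counting interval 243 to 53600) and those of the mast cell tryptase Tpsb2 399-fold higher (136 to 1940). The mast cell chymase Cma1 rose by a log2 fold change of 6.59, Stfa1 by 6.02, Dab2 by 5.63, Fam71b by 5.58, Ceacam16 by 5.37, Cdh17 by 5.28 and the RNA-binding protein gene Igf2bp3 by 5.16. Igfbp7, a secreted binding protein gene, rose from 0.943 ± 0.333 to 32.9 ± 12.5 CPM (SD, n = 4; 5.12 ± 0.39 SE, edgeR adjusted p = 3.83e-06). The largest falls were of the eosinophil genes Ear6, Ear1 and Epx (at least 656-fold, at least 619-fold and a log2 fold change of -9.94), Zfp618 (at least 450-fold), Scml2 (at least 433-fold), Foxa3 (at least 344-fold), the transporters Slc27a6 (562-fold by counts, 192 to 2730) and Slc16a12 (-8.58), and the imprinted gene Phlda2 (-7.19). Without Yy1+/+ replicate 2, Ear6 was at least 325-fold and Ear1 at least 347-fold lower and Epx had -8.44, and the reads of Epx in Yy1-/- Smc3+/- came from replicate 1 alone. Without Yy1-/- Smc3+/- replicate 2, Dab2 had 4.2. Rises were more than 1.5 times larger without Yy1+/+ replicate 1 for Ednrb (11.21), Stfa1 (7.68), Dab2 (6.49) and Cdh17 (6.2), without replicate 2 for Fam71b (6.42) and Igf2bp3 (5.86), and without replicate 4 for Cma1 (7.7) and Tpsb2 (9.33). Falls were so without Yy1-/- Smc3+/- replicate 2 for Slc16a12 (-11.9), replicate 3 for Phlda2 (-8.33) and replicate 4 for Slc27a6 (-11.91). Dab2 lost its call with limma-voom (adjusted p = 0.306, in a range from 0.00042 to 0.306), as did Stfa1 (0.115, in a range from 4.87e-07 to 0.115) and Epx (0.177, in a range from 7.25e-05 to 0.177), and Ear6 and Ear1 lost theirs with the Xist level as a covariate (0.104 and 0.0952, in ranges from 3.48e-07 and 3.35e-07), as did Dab2 (0.0621).

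Of the 43 lists, 19 passed camera in Yy1-/- Smc3+/- against Yy1+/+, 12 higher and 7 lower, and with an estimated correlation only the stem cell genes did. The number of changed genes was between 3835 and 5313 over the alternatives other than the Xist covariate and a 2-fold minimum, with which it was 2900.

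The stem cell and mitotic genes moved alike in both genotypes labelled Yy1-/-, and so did most other changed genes. Against Yy1+/+, 4130 genes changed in the same direction in both, 1751 higher and 2379 lower, and 1, the immunoglobulin kappa segment Igkv17-127, chosen after its values were seen, changed in opposite directions. These were 70.6% of the genes changed in Yy1-/- and 83% of those changed in Yy1-/- Smc3+/-. Independent changes in these numbers would give 357.9 shared rises and 524.1 shared falls. The log2 fold changes correlated at r = 0.842 across genes, which are not independent replicates. Both comparisons use the same Yy1+/+ libraries: simulated groups without any change gave a median of 0 shared genes and r = 0.499 in 20 draws. Few genes can be called where nothing changes, so that 0 does not show how many shared genes the common controls add. Simulated groups with the same change in both gave a median of 3888 shared genes and r = 0.912. The highest of these draws, 3971, lay below the 4130 observed, and the draws took genes as independent. When the 4 Yy1+/+ libraries were split between the comparisons, between 1463 and 1833 genes were shared and r was between 0.695 and 0.722.

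**Figure D3:**
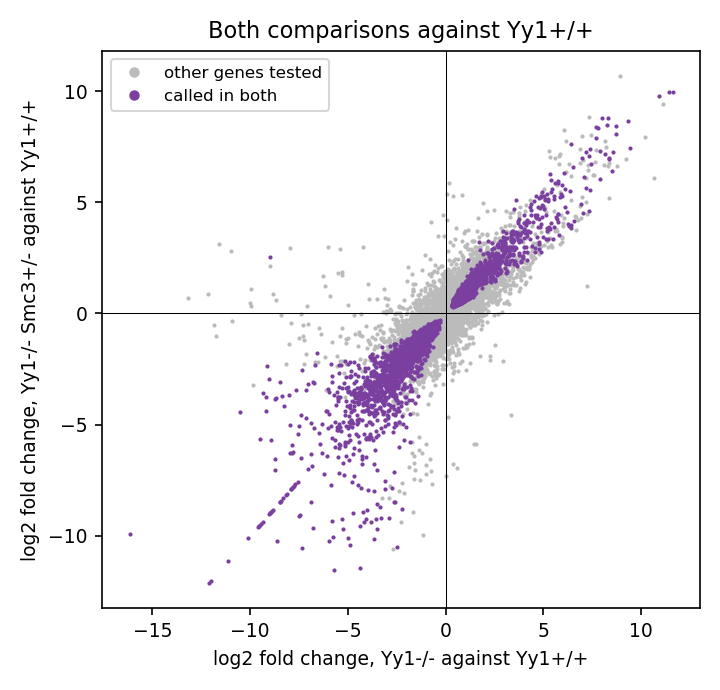
Log2 fold changes against Yy1+/+ of all 16649 tested genes (points), with Yy1-/- on the horizontal axis and Yy1-/- Smc3+/- on the vertical axis, and genes that changed in both in purple. The correlation is 0.842 across genes, and 4130 genes changed in the same direction in both.

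The comparison of Yy1-/- Smc3+/- with Yy1-/- asks what sets these 2 labels apart. Stem cell genes (median log2 fold change 0.07, camera adjusted p = 0.781) and mitotic genes (median 0.02, camera adjusted p = 0.848) did not pass the list test between these genotypes. By edgeR 6 of 16649 genes changed, all higher in the libraries labelled Yy1-/- Smc3+/-, and 5 of the 6 are pseudogene copies of the ribosomal protein genes Rplp0 and Rps7. The sixth is Rab35, a small GTPase of endosomal recycling. At an unadjusted p under 0.05 there were 1076 genes, and limma-voom called 4, limma on log2 TPM 6 and DESeq2 53, while 2% of the genes had no overlap between libraries, against 2.9% by chance. Without the libraries with residual Yy1 reads, which leaves a pair of Yy1-/- libraries, edgeR called 311 genes, 34 higher and 277 lower.

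Rab35 (ENSMUSG00000029518.15, chromosome 5:115631908-115647736, GRCm38) rose from 16.2 ± 3.72 CPM (SD, n = 4) in Yy1-/- to 51.2 ± 12.9 in Yy1-/- Smc3+/- (log2 fold change 1.66 ± 0.23 SE, edgeR adjusted p = 0.0178). This call was lost in 9 of 26 alternatives, in a range from 9.41e-09 to 0.331, including log2 TPM (0.0505), a fit of only the 2 genotypes (0.0722), the Xist covariate (0.331), the omission of the pair of libraries that stand apart (0.143), and the omission of Yy1-/- replicate 1 (0.0991), 2 (0.0578) or 3 (0.0843) or of Yy1-/- Smc3+/- replicate 1 (0.0786) or 2 (0.0965). In these 9 the log2 fold change lay between 1.4, with the Xist covariate, and 1.75.

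The pseudogene copies, chosen after their values were seen, were near-identical to their parents, so their counts are uncertain. Gm9625 (chromosome 13:67810246-67811200, GRCm38) rose by a log2 fold change of 5.74 ± 0.27 SE (edgeR adjusted p = 2.4e-07) and was 97.4% identical to Rplp0 mRNA. Gm8730 (8:102864845-102865798) rose by 4.87 ± 0.25 (3.88e-07) at 98.7% identity, Gm14165 (2:152353615-152354566) by 5.29 ± 0.49 (7.53e-07) at 97.2% and Gm6278 (16:85644252-85645023) by 4.56 ± 0.50 (1.62e-05) at 92.8%. Gm6472 (X:152909505-152910155) rose by 2.69 ± 0.23 (6.3e-05) and was 99.4% identical to Rps7 mRNA. The summed Rplp0 copies had 10.8, 14 and 444 CPM in Yy1+/+, Yy1-/- and Yy1-/- Smc3+/-, while Rplp0 itself had 1464, 2366 and 1533 CPM. The Rps7 copy had 16.6, 21.6 and 139 CPM, and Rps7 itself 536.7, 799.1 and 514.7 CPM.

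**Figure D4:**
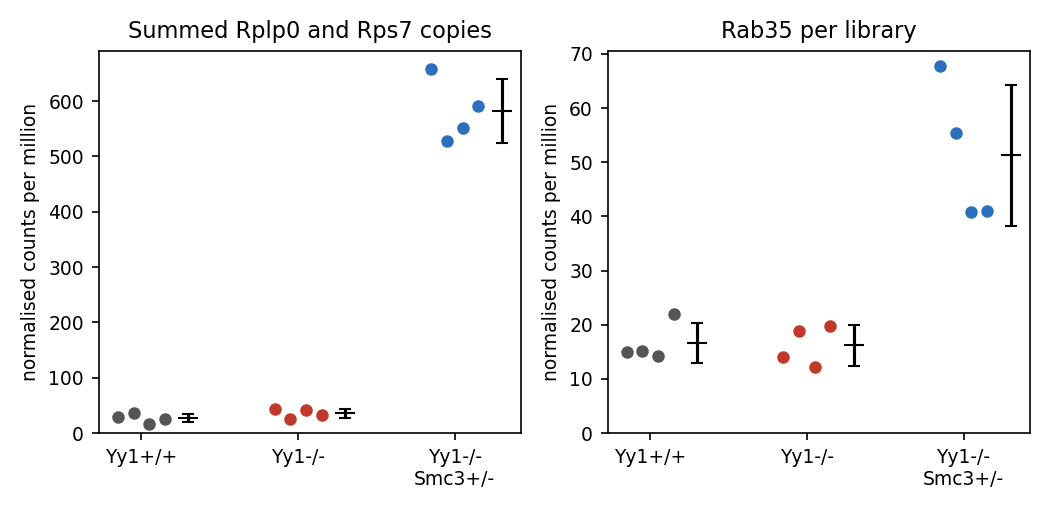
Summed level of the Rplp0 and Rps7 copies (left) and level of Rab35 (right) in TMM-normalised CPM for each library (points) by genotype, with the mean and SD of n = 4 libraries. The summed copies lie between 528 and 659 in Yy1-/- Smc3+/- and at or below 43.3 in all other libraries.

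Small shifts across lists were seen between the Yy1-/- genotypes, with 0 members changed by edgeR over all genes in any of the lists. Y-linked reads were present in every library labelled Yy1-/- Smc3+/- (130, 135, 28.7 and 162 CPM) but, among Yy1-/- libraries, only in replicate 3 (38.9 CPM). The sex of the animals was therefore not separated from the label for the lists of this comparison. Genes for cytosolic ribosomal proteins had a median log2 fold change of -0.27 (camera adjusted p = 1.26e-19), interferon-stimulated genes -0.50 (1.05e-15), mitochondrial ribosomal proteins -0.16 (2.03e-07) and oxidative phosphorylation -0.16 (3.07e-07), and B lineage genes 0.67 (5.3e-06). These 5 lists passed camera in all alternatives in which they were tested with the preset correlation, and each had adjusted p = 0.63 with an estimated correlation. Adjusted over the list alone, 2 ribosomal protein genes fell, Rplp0 and Rps7 (both -0.63 ± 0.15 SE, adjusted p = 0.0439), which are the parents of the copies, and 6 B lineage genes rose, among them Rag2 (3.72), Ighd (2.36), Ebf1 (2.03), Cd79a (1.16) and Sdc1 (0.8), all chosen after their values were seen.

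Monocyte genes had a median of -1.02 (camera adjusted p = 3.38e-07), immediate early genes 0.75 (0.000213) and neutrophil genes -0.62 (0.00169), each with adjusted p = 0.63 with an estimated correlation. The monocyte call was lost with a surrogate variable (0.116, in a range from 5.25e-21 to 0.116), the immediate early call without Yy1-/- Smc3+/- replicate 1 (0.397) or the libraries with residual Yy1 reads (0.0776, in a range from 2.04e-08 to 0.64), and the neutrophil call without Yy1-/- replicate 2 (0.123) or Yy1-/- Smc3+/- replicates 2 (0.0984) or 4 (0.0573), in a range from 1.51e-11 to 0.379. With the Xist covariate the direction of the immediate early (0.64) and neutrophil (0.379) lists turned. In all, 14 lists passed camera, 4 higher and 10 lower, with 0 passing with an estimated correlation and 0 by fry.

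No gene that changed in Yy1-/- against Yy1+/+ moved back in Yy1-/- Smc3+/- by edgeR: 0 genes changed in both comparisons in opposite directions. At an unadjusted p under 0.05, 1076 genes differed between the Yy1-/- genotypes, and DESeq2 counted 33 genes that moved back. Without Yy1-/- Smc3+/- replicate 4 the count was 1. It was 257 without the libraries with residual Yy1 reads, a fit that kept only Yy1-/- replicates 1 and 2. Replicates 1 and 2 of both genotypes set against replicates 3 and 4 gave 236 changed genes. The count of 257 is therefore not separated from this difference between replicates. The log2 fold changes of the 2 comparisons correlated at r = -0.367 across genes, while simulated groups in which Yy1-/- and Yy1-/- Smc3+/- were alike gave r = -0.211 with an SD of 0.015. Each gene was drawn independently, so this SD leaves out the spread from genes that move together. The gap between the 2 values of r therefore cannot be read as a partial return. When the Yy1-/- libraries were split between the comparisons, r was between -0.245 and 0.053. With replicates 3 and 4 in the first comparison and 1 and 2 in the second, 235 genes changed in the second, and 46 genes changed in both in opposite directions and 17 in the same direction. In the other 5 ways of splitting, 0 changed in opposite directions.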

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

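The tests of all explanations in this part were chosen after the result they weigh was seen. In 143 groups of 4 libraries, 18 had a highest or lowest library set apart from the other 3 by Dixon's ratio at its 95% critical value, and chance alone would set apart about 7.2.

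In Yy1-/- Smc3+/- libraries, reads at pseudogene copies of Rplp0 and Rps7 were many times higher than in the other genotypes, with Rab35 the other changed gene against Yy1-/-. Sex of the donor animals is argued against, because the summed copies reached at most 43.3 CPM in any library outside this genotype, some of which held Y-linked reads, and 528 to 659 CPM in all 4 within it, of which replicate 3 held Xist reads. Reads of Rplp0 and Rps7 counted at their copies remain a candidate explanation, since Rplp0 alone had a log2 ratio of -0.63 against Yy1-/- but Rplp0 and its copies together -0.27, and Rps7 alone -0.63 but the sum -0.33, at or near the median of the 81 ribosomal protein genes of -0.27 (SD 0.09). A strain variant near Rab35 and Rplp0 also remains open. Of the other genes within 10 Mb of Rab35, 2.7% (8 of 294) had p under 0.01, against 1.1% elsewhere (186 of 16347). The two-sided Fisher's exact p was 0.0222, with a window chosen after the values were seen. That test took neighbouring genes as independent, and its window was drawn around Rab35 alone, so it does not speak to the Rps7 copy. The design names a biological difference, the Smc3+/- label, which was not tested apart from these explanations.

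Stem cell genes were lower and mitotic genes higher in Yy1-/- than in Yy1+/+ libraries. Sex of the donor animals is argued against, because in the 5 libraries without Y-linked reads (2 Yy1+/+ and 3 Yy1-/-) the median log2 fold changes were -2.31 and 0.83, against -2.13 and 1.07 in all 8, with no overlap between genotypes in the mean log2 level of stem cell genes (5.95 to 6.04 and 3.61 to 4.02) or mitotic genes (6.1 to 6.78 and 7.16 to 7.42), although with 5 libraries only 33 of 44 called stem cell genes and 6 of 46 mitotic genes passed edgeR again, with 44 and 46 in the same direction. Whether the main cell type had a lower share, with every other type alike, could not be decided. Over 8 lists of markers of other types (202 genes, without stem cell genes), medians ran from -1.37 for erythroid to 2.01 for monocyte genes. A permutation of genes between the lists gave p = 1e-05, the smallest that 100000 permutations can give. Without the erythroid and megakaryocyte lists the permutation p was 0.00019. These permutations took genes as independent, while the estimated correlation within lists was 0.512 for neutrophil and 0.438 for monocyte genes. Tests run before them on only the members with a mean under 5 CPM did not pass. Their permutation p was 0.0559 for the 8 lists, 0.2 for the 6 and 0.367 for B lineage against monocyte genes. A look at markers low in Yy1+/+ was set aside because it selects on the control's level. Different changes in the shares of single types remain open, because the sort gate removes lineage-positive cells but leaves stem cells and progenitors together, with Cd48 of progenitors higher in Yy1-/- (log2 fold change 1.75 ± 0.17 SE, edgeR adjusted p = 2.05e-05) and Procr of stem cells lower (-2.09 ± 0.23, edgeR adjusted p = 4.52e-05). The lower Yy1 level, the difference that the design names, stays among the open explanations as a change within cells or in their proportions.

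Yy1+/+ replicate 2 was set apart by a TMM factor of 0.917 against 1.05 to 1.08 in the other 3 libraries. Its Yy1 level was 41.3 CPM against 33.9 to 34.2, and its level of Rap1b, a platelet GTPase gene, 473 CPM against 227 to 259. In Yy1+/+ replicate 3 the light chain gene Iglc2 had 198 CPM against 22.2 to 48.4 in the others. In Yy1+/+ replicate 4 Rab35 had 22.1 CPM against 14.3 to 15.2.

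Yy1-/- replicate 1 had 594 CPM of the mitochondrially encoded mt-Cytb against 938 to 999 in the other 3 libraries. Yy1-/- replicate 3 had reads of the Y-linked genes Eif2s3y (23.1 CPM), Ddx3y (8.62 CPM), Uty (4.15 CPM) and Kdm5d (3.03 CPM), with 0 CPM of each in the other 3, beside 79.8 CPM of Xist. Its Cd34 level was 1160 CPM against 942 to 961.

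Yy1-/- Smc3+/- replicate 3 had 4.45 CPM of Yy1 against 0.772 to 0.944 in the other 3 libraries, and 107 CPM of Xist against 0 to 3.58. It had 10100 CPM of Mpo against 565 to 981, 1650 CPM of the granule protease gene Ctsg against 448 to 624, 211 CPM of Nkg7 against 32.6 to 39.6 and 128 CPM of Car1 against 0 to 4.67. In Yy1-/- Smc3+/- replicate 1 Epx had 0.75 CPM against 0 in the others.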

How the results depend on the processing

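Leaving out the libraries with residual Yy1 reads, leaving out those that stand apart, leaving out immunoglobulin genes, the granule gene covariate and the block of replicates were chosen after the data were seen. Nothing in the labels pairs libraries of different genotypes, and no paired analysis was made. With replicates 1 and 2 against 3 and 4 of the 2 genotypes labelled Yy1-/- as a block, edgeR called 6013, 5248 and 6 genes in the 3 comparisons. The 6 were the same genes as without the block, 4352 genes were shared and 0 moved back, with 1147 genes at an unadjusted p under 0.05 in the last comparison. Apart from single omissions, named genes kept their direction and call in 3205 tests and lost the call in 37 for Yy1-/- against Yy1+/+, and in 3193 and 64 for Yy1-/- Smc3+/- against Yy1+/+, and lists did so in 356 and 17 and in 305 and 17. Between the 2 genotypes labelled Yy1-/-, named genes did so in 14 and 4, and lists in 221 and 13, with 3 that turned. With single omissions there, named genes did so in 3 and 5, and lists in 98 and 14. The cause of the changes below was not tested unless stated.

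With DESeq2, 53 genes changed between the genotypes labelled Yy1-/- (34 higher, 19 lower) and 33 moved back, and it gave Yy1 no adjusted p. The edgeR 3 style and the granule gene covariate each gave 1 gene that moved back. With log2 TPM the Smc3 log2 fold change in Yy1-/- was 0.24 (adjusted p = 0.346). The Xist covariate left 2427 changed genes in Yy1-/- Smc3+/- against Yy1+/+ and 2183 shared genes. It turned the direction of 3 lists between the genotypes labelled Yy1-/-, to adjusted p = 0.64 for immediate early, 0.379 for neutrophil and 0.459 for megakaryocyte genes. A 2-fold minimum left 3399 and 2900 changed and 2334 shared genes, by its construction. Without the libraries with residual Yy1 reads, Smc3 in Yy1-/- had 0.39 (adjusted p = 0.168), Yy1 between the genotypes labelled Yy1-/- turned to 0.18 (adjusted p = 0.926), 311 genes changed there and 257 moved back. That fit kept only Yy1-/- replicates 1 and 2. With an estimated correlation 2, 1 and 0 lists passed, with fry 22, 19 and 0, and with fry in either direction 42, 41 and 0. In Yy1-/- against Yy1+/+ the replication, interferon, DNA repair, immediate early, neutrophil and monocyte lists passed camera but not fry. The cohesin, pentose phosphate, fatty acid oxidation, apoptosis, adhesion, and TGF-beta, Notch and Wnt lists passed fry but not camera. Splitting the shared controls left a median of 1721 shared genes over the 6 ways (1463 to 1833), with fewer libraries in each comparison. Single omissions gave Smc3 log2 fold changes in Yy1-/- from 0.40 to 0.63 and 0 to 1 gene that moved back.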

Other observations

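The tests of the origin of immunoglobulin transcripts and of other splits of the libraries were written down after the results were seen. Genes by which stem cells attach to each other and to their niche, and genes of early progenitors, changed in both directions in Yy1-/- against Yy1+/+. Of 28 adhesion genes 6 rose and 9 fell (camera adjusted p = 0.333), with Jam2 and Jam3, junctional adhesion molecules, lower by log2 fold changes of -5.25 (-5.94 without Yy1-/- replicate 3) and -5.46 (-6.4 without replicate 2) and Robo4 by -3.97. Of 23 genes of multipotent and lymphoid-primed progenitors 4 rose and 9 fell (camera adjusted p = 0.553), with Cd48 (1.75), Il7r and Cd52 among the risers and Cd27 lower by -1.25. Of 40 genes of the TGF-beta, Notch and Wnt pathways 1 rose and 13 fell (camera adjusted p = 0.0879), the riser being Id2 (2.35), an inhibitor of lineage transcription factors. Of 47 genes of KIT and cytokine receptor signalling 8 rose and 12 fell (camera adjusted p = 0.367), with Csf2rb, the common beta receptor chain, higher by 1.56 and Kit lower by -2.12. Of 26 quiescence and cell cycle inhibitor genes 3 (Cdkn2a, Cdkn2c and Gas2l3) rose and 8 fell (camera adjusted p = 0.553), with Cdkn1c lower by -2.28 and Cdkn2a at least 31.9-fold higher.

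Metabolic genes of Yy1-/- cells also moved both ways within their lists. Of 27 glycolysis genes 7 rose and 8 fell (camera adjusted p = 0.675), with Gapdh higher by a log2 fold change of 0.99 ± 0.14 SE (edgeR adjusted p = 0.000252) and Ldhb lower by -4.78 ± 0.44 (1.29e-05). Of 23 fatty acid oxidation genes 4 (Acadl, Acaa1a, Eci2 and Etfa) rose and 7 fell (camera adjusted p = 0.189), with Acadm, the medium-chain dehydrogenase, lower by -1.78 ± 0.21 (edgeR adjusted p = 7.5e-05). Of 41 antioxidant genes 13 rose and 12 fell, with the glutathione transferases Gsta4 and Gstm5 lower by -4.19 and -2.36. Of 26 genes of the tricarboxylic acid cycle 6 rose and 4 fell (camera adjusted p = 0.675), the latter being Suclg2 (-2.93), Sucla2, Sdha and Sdhc. The list of mast cell, basophil and eosinophil genes, 5 of 23 higher (Gzmb, Mcpt4, Cma1, Tpsb2 and Cd200r3) and 8 lower (camera adjusted p = 0.643), had a median near 0 (-0.05) and a mean of -1.30. For B lineage genes the median was 0.20 and the mean -0.20, with camera in the direction of lower (adjusted p = 0.693), and for stromal genes the median was 0.05 and the mean 0.41, also with camera in the direction of lower. In the libraries labelled Yy1-/- Smc3+/- interferon-stimulated genes had a median of 0.07 against Yy1+/+ with camera in the direction of lower (adjusted p = 0.885).

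Immunoglobulin transcripts were among the most abundant in every library. Igha, the heavy chain of IgA, had 6960 ± 2980 CPM (SD, n = 4) in Yy1+/+, 8830 ± 5860 in Yy1-/- and 12700 ± 1830 in Yy1-/- Smc3+/-, and it was the most abundant gene in 8 of 12 libraries. RNA of mature B cells is argued against as the source, because Ms4a1, Pax5 and Ighd reached at most 3.2 CPM in any library. RNA of plasma cells may be the source: across the 12 libraries Igha followed the mean of the plasma cell markers Jchain, Mzb1, Derl3, Tnfrsf17, Prdm1 and Irf4 (Pearson r = 0.91, permutation p = 2e-05; Spearman rho 0.92, permutation p = 0.00015; r = 0.92 without the 2 libraries farthest from the median and 0.89 within genotypes), with Jchain at 1880, 1790 and 2940 CPM in the 3 genotypes, although the sort for lineage-negative cells with Sca1 and c-Kit on their surface would be expected to remove plasma cells. No biological explanation in the cells of the gate was tested.

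Igkc changed only in Yy1-/- Smc3+/- against Yy1+/+ among the 3 comparisons (log2 fold change 1.02 ± 0.32 SE, edgeR adjusted p = 0.0298), and its difference between the genotypes labelled Yy1-/- did not pass (0.76, edgeR adjusted p = 0.756). The most frequent V segment was 1 of 9 different segments across the 12 libraries for the heavy chain, with 7.9% to 52.9% of the V reads, and 1 of 9 for the kappa chain, with 10.4% to 22.4%.

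Each comparison was repeated for all splits of its 8 libraries into groups of 4. Chance is argued against for the 5854 genes changed in Yy1-/- against Yy1+/+ (1 of 35 splits gave as many, highest other 1). The same holds for the 4975 in Yy1-/- Smc3+/- against Yy1+/+ (1 of 35, highest other 2). So few splits cannot exclude chance, and mixed splits hold the genotype difference as spread within their groups. For a count of 6 genes between the genotypes labelled Yy1-/-, chance remains open (3 of 35 gave as many). This count does not ask which genes were called, and the summed copies of Rplp0 and Rps7 had 528 to 659 CPM in one genotype and at most 43.3 CPM in the other. The highest other, 236, came from the split that set replicates 1 and 2 of both genotypes against replicates 3 and 4, which points to a structure of the samples beside the genotype. With this structure as a block, edgeR called the same 6 genes. For the number of lists chance cannot be excluded: 22 in Yy1-/- against Yy1+/+ (2 of 35, highest other 22), 19 in Yy1-/- Smc3+/- against Yy1+/+ (7 of 35, highest other 24) and 14 between the genotypes labelled Yy1-/- (22 of 35, highest other 20). In 100 regroupings of all libraries, chance is argued against for the 4130 genes shared in direction (1 of 100, highest other 1), with the same limit of mixed groups. For the 0 genes that moved back the regroupings decide nothing, since each of the 100 gives at least 0 (highest other 3).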
